A study of Mus musculus with 48 samples.

How the data were processed

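Single-cell RNA-seq was analysed for 48 mouse cells, each captured on a Fluidigm C1 device from embryoid bodies in which Mesp1 had been induced with doxycycline. The values deposited by the authors are 1 table with a column per cell. They are treated as FPKM: the table does not name its unit, but the submitters' processing notes name Cufflinks 2.2.1.0, which gives FPKM, and the deposited values are not whole numbers and sum to different totals per cell. The notes also name CASAVA 1.8.2, TopHat 0.7 and build mm10, with no role or order given. The gene annotation, read filters and any scaling across cells are not given in the sources used here.

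The table held 23746 rows and 23284 gene symbols. Rows of the 240 symbols found on several rows were summed. Of the rows, 7041 were 0 in every cell, and 66.7% of all values were 0. Of the symbols, 20911 were found in the GENCODE M21 annotation of GRCm38, from which coordinates were taken, and 1976 more matched as older symbols. All 314 genes of the fixed lists were found, 2 of them under older symbols (Foxf1a for Foxf1 and Sfpi1 for Spi1). Column names were matched to the cells' titles. The number in each title was read as the capture site, which the labels do not state. FPKM values divide by transcript length, so rows of very short RNAs can take large values. FPKM summed to between 480821 and 12864440 per cell, and to between 412418 and 701420 without 779 symbols of short RNAs. More than 50% of the sum came from short RNAs in 11 cells. FPKM keeps no read count, so depth is unknown and no interval for a level was given.

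The labels gave 1 group and no culture or preparation, so cells were described and not tested. A gene counted as detected at 1 FPKM or more. Shares of cells carry exact Clopper-Pearson 95% intervals, and for 0 of 48 cells the limit of 3 counts (6.25%) is given, which covers counting error and not transcripts lost in a cell. No cell was removed. No doublet caller was run, because the table holds no counts and few cells, so a pair of cells captured together could not be recognised. Scores and correlations used log2(FPKM + 1), with a pseudocount of 1 FPKM.

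Variable genes had a squared coefficient of variation over 2-fold (0.3 in log10) above a local regression on the mean with a span of 0.4, among genes with a mean of at least 5 FPKM that were detected in at least 5 cells. List coordination was the mean pairwise Spearman correlation of members detected in at least 5 cells. List scores were means of z-scored members, with shared members removed from both lists of a pair. Each value was ranked among 10000 random lists of the same size, drawn from 10598 genes in 20 bins of mean level, and called at a percentile of 98 or more (for relations also 2 or less). For relations each list was replaced in turn and the less extreme percentile kept. The 54 pairs of 11 cell type and state lists formed 1 family. Clusters were made by Ward's method on 5 principal components of the 500 genes with the largest excess variability, with the number of clusters from 2 to 6 chosen by the mean silhouette and set beside 100 matrices with each gene permuted over cells. Clusters take the name of a cell type list, not of a state list, and only with at least 3 of its markers among their 10 leading genes.

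The 23 gene lists (cell types, epithelial and mesenchymal states, 4 signalling responses, 2 cell cycle phases, glycolysis and hypoxia, immediate early and heat shock genes, p53 and apoptosis, housekeeping), thresholds and tests were fixed before the data were examined. So was the rule for named genes: Mesp1, Kdr and Pdgfra; per list, up to 4 members detected in most cells and the member with the largest excess variability; the 25 genes with the largest excess variability; 5 leading genes per cluster as descriptions only; and Hox genes as a count with 4 named. Further list members (such as T, Hand1, Isl1, Nkx2-5, Cdh5, Pecam1, the globins, Tbx6, Msgn1, Myf5, Myod1, Myog, Myh6, Nppa, Pou5f1, Sox2, Esrrb, Hes5, Heyl and Dll4) were named after their values were seen. Some genes that the rule would name are not reported here.

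Settings fixed in advance and varied 1 at a time were the detection threshold (0.1 and 10 FPKM), the pseudocount (0.1), the filter on members (any, or at least 12 cells), the mean filter, the scaling (each cell to a total of 1000000), the cells (without 7 cells under 5189 detected genes, 3 median absolute deviations below the median), the covariates (number of detected genes, cell cycle scores) and the clustering. Removal of short RNA rows, rescaling without them, the split at capture site 48, regression on the capture site and the few-gene cells for Mesp1 and the cell cycle were added after the data had been seen.

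The procedures were tested on simulated data, made for lists, relations and clusters by shuffling each gene over cells (10598 genes, 10570 for clusters) and for variable genes by drawing gamma values around the trend (6266 genes). Planted coordination was called in 9 or 10 of 10 lists at every size and strength tried. Among 100 unplanted lists per size, 2 were called at 5 members, 1 at 8, 7 at 13 and 1 at 25. Planted opposed lists were called in 26 of 30 pairs and independent ones in 1 of 29. Of 100 genes each, 77 were called at 3-fold and 96 at 6-fold above the trend, beside 77 of 6066 genes at the trend (1.27%). A planted group of 12 cells, with 60 genes raised by more than 8-fold, was recovered in full. Short RNA rows were left out of that simulation, and the planned clustering kept them. The result therefore covers a strong group without such rows and not the planned clustering as run. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and scikit-learn 1.9.0.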

Results

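RNA was sequenced from 48 single mouse cells to describe which mesodermal programmes embryonic stem cell derivatives express after a pulse of Mesp1, a basic helix-loop-helix transcription factor of nascent cardiovascular mesoderm. The embryonic stem cells (strain 129P2/OlaHsd) carried a doxycycline-inducible Mesp1 and were cultured as embryoid bodies, aggregates that differentiate in suspension. Doxycycline was present at 500 ng/ml between days 2.25 and 3.25. At day 4, cells that excluded propidium iodide, a dye of dead cells, were sorted and captured singly on a Fluidigm C1 microfluidic device. The labels put all 48 cells in 1 group and name no separate cultures, so the group stood as 1 sample, and neither uninduced cells nor a second preparation were there for a comparison. No p-value was made from cells. Relations are described by their percentile among 10000 random gene lists of matched expression, and the intervals given for shares of cells cover counting error only.

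A median of 6212 genes reached 1 FPKM (fragments scaled by transcript length and by the number mapped) per cell, with a range from 4788 to 7010. Of the 12 housekeeping genes, 11 (among them Actb, Gapdh and Eef1a1) were detected in all cells, with a median of 2931 FPKM for Actb. Hprt, the remaining one, reached 1 FPKM in 31 cells and was listed at 0 in 13, so a value of 0 is reported here only as listed. The number of detected genes fell with the number in each cell's label, read here as its capture site (Spearman's rho = -0.82, Pearson's r = -0.82 over 48 cells, r = -0.80 without the 2 cells at the farthest sites). It fell in both parts of the device, with rho = -0.40 over the 25 cells at sites up to 48 and rho = -0.84 over the 23 cells at higher sites, whose medians were 6506 and 5711 genes. Sequencing depth per cell is unknown, since the table holds no counts. No pair of cells correlated above 0.68 on the log2 scale (median 0.59), so no library appeared to have been deposited more than once.

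**Figure D1:**
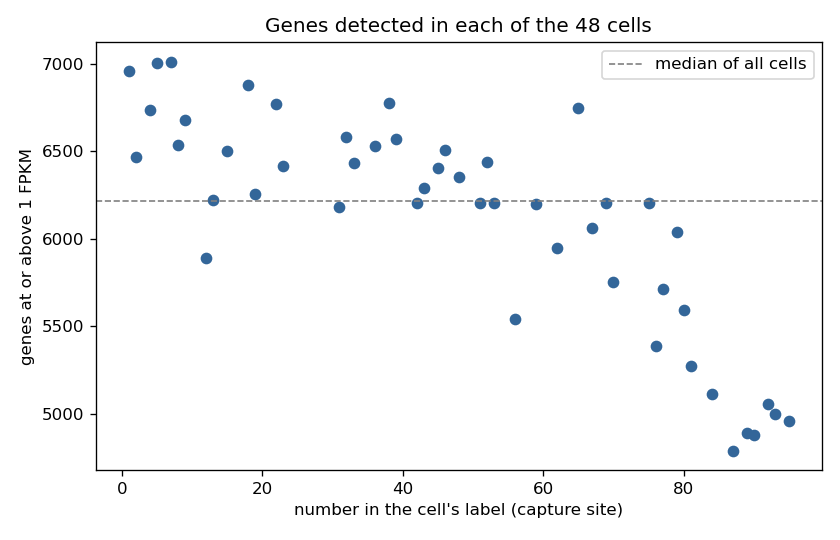
Genes at or above 1 FPKM (vertical axis) in each of the 48 cells against the number in the cell's label (horizontal axis); each point is a cell and the dashed line is the median of 6212. Cells at the highest numbers had the fewest detected genes, down to 4788.

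Mesp1, the induced gene (GRCm38 chromosome 7, 79792241 to 79793788, minus strand), reached 1 FPKM in 30 of the 48 cells (62.5%, exact Clopper-Pearson 95% interval 47.4% to 76.05%). Its median was 7.66 FPKM, with quartiles of 0 and 34.2 FPKM and a maximum of 254 FPKM, and 15 cells listed it at 0. Mesp2, its neighbouring paralogue, was detected in 13 cells. Sites up to 48 and higher sites gave Mesp1 in 16 of 25 and 14 of 23 cells. The table holds a single Mesp1 value per cell, which does not separate transcripts of the inducible copy from those of the endogenous gene.

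Primitive streak and nascent mesoderm genes were broadly detected: 12 of 15 members of the primitive streak list reached 1 FPKM in at least 25% of cells. Lhx1 was detected in 38 cells, Eomes, a T-box factor needed for mesoderm and endoderm formation, in 35, and Mixl1 and Snai1, the latter a repressor of E-cadherin, in 30 each. Their medians were 14.3, 28.2, 21.6 and 15.7 FPKM. T (brachyury; chromosome 17, 8434423 to 8442496, plus strand) was detected in 26 cells with a median of 1.90 FPKM and a maximum of 473 FPKM. Cer1, a secreted antagonist of Nodal and BMP signals, had the largest excess variability of the list and was detected in 17 cells at up to 1435 FPKM.

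Cardiac and lateral plate mesoderm genes were detected at the level of early regulators, with 10 of 20 members in at least 25% of cells. Fgf10 was detected in 38 cells, the zinc finger factors Gata4 and Gata6 in 33 cells each, Pdgfra in 31, Hand1 in 26 and Isl1 in 25. Hand1 was the most variable member, with a median of 5.78 FPKM and a maximum of 523 FPKM. Nkx2-5, a cardiac homeobox gene, was listed at 0 in all 48 cells; counting alone would allow up to 6.25% of cells with a value above 0, which is no limit on cells that express it. Of the contractile genes of cardiomyocytes, 3 of 14 reached the 25% mark: Tpm1, a tropomyosin not restricted to muscle, in 47 cells, the atrial light chain Myl7 in 17 and Tnni1 in 12. Myl4 was detected in 7 cells, and Myh6 and Nppa in none.

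Paraxial mesoderm genes were represented by 9 of 18 members in at least 25% of cells, led by Cyp26a1, a retinoic acid-degrading enzyme, in 37 cells (median 40.6 FPKM), Pdgfra in 31, the retinoic acid-producing enzyme Aldh1a2 in 21 and Dll3 in 20. Aldh1a2 had the largest excess variability in the list and reached 276 FPKM. The presomitic factors Tbx6 and Msgn1 were detected in 13 and 5 cells. Among 39 Hox genes, 5 were detected in 5 or more cells and 28 in none; Hoxb1 was detected in 35 cells, Hoxb3 in 19 and Hoxb2 in 16. The skeletal myogenic list had 0 of 10 members in at least 25% of cells: Eya1 was detected in 10 cells, Pax3 in 7 and Met in 2, while Myf5, Myod1 and Myog were below 1 FPKM in every cell.

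Endothelial and blood genes were also examined. Of 21 endothelial members, 3 reached the 25% mark: Etv2, an ETS factor at the top of the hemangiogenic programme (chromosome 7, 30633616 to 30635852, minus strand), in 26 cells, and Kdr and Egfl7 in 22 each, followed by Lmo2 in 11. Etv2 ranged from 0 to 907 FPKM with a median of 1.71 FPKM. Cdh5 and Pecam1, junction genes of formed endothelium, were below 1 FPKM in every cell. The hematopoietic list had 1 of 16 members at the 25% mark, Gata2 in 15 cells; Runx1 was detected in 10 cells, Myb in 4 and Ikzf1 in 2, and the globin genes of the list were listed at 0 throughout. Smooth muscle and mural genes had 3 of 8 members, with Rgs5 in 29 cells (the most variable member, up to 474 FPKM), Pdgfrb in 15, Des in 13 and Acta2 in 8.

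Members of the pluripotency, endoderm and neurectoderm lists were also detected. Lin28a, Dnmt3b and Nanog were in nearly all cells, so their detection does not set another cell type apart. The pluripotency list had 9 of 14 members in at least 25% of cells: Lin28a in 48 cells, the de novo methyltransferase Dnmt3b in 47, Nanog in 46 and the Nodal co-receptor Tdgf1 in 33, with medians of 119, 25.5, 9.28 and 54.6 FPKM. Pou5f1 was detected in 26 cells, Sox2 in 18 and Esrrb in 6. The endoderm list had 2 of 13 members, Trh, the thyrotropin-releasing hormone precursor, in 35 cells and Foxa2 in 12; Apoa1 was detected in 3 cells, Spink3 in 2 and Sox17 in 1. The neurectoderm list had 1 of 11, Otx2 in 24 cells, with Pax6 in 5, Nes in 4, and Sox1 and Pou3f1 in 2 each.

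**Figure D2:**
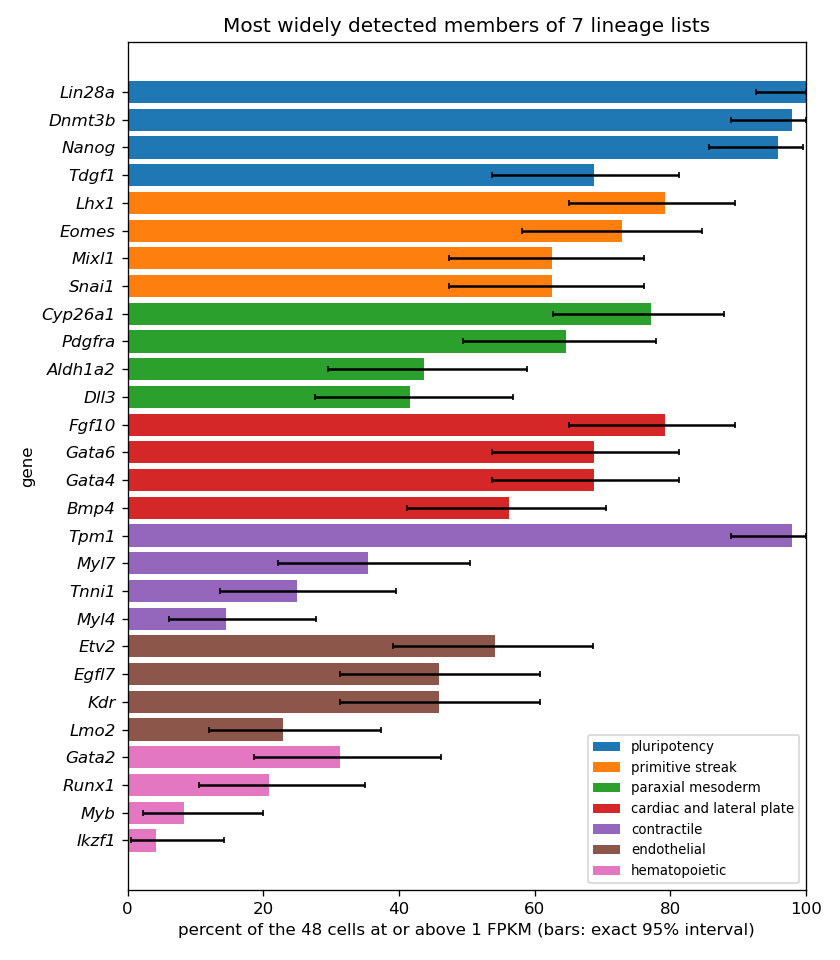
Percent of the 48 cells at or above 1 FPKM (horizontal axis) for the most widely detected members of 7 lineage lists; whiskers are exact 95% intervals and cover counting error only. Pdgfra belongs to both mesoderm lists and is drawn once. Lin28a, Dnmt3b and Nanog exceeded 95%, while hematopoietic members stayed at or below 31.3%.

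Epithelial and mesenchymal genes were both detected. Among 10 epithelial genes 5 were in at least 25% of cells, with the keratins Krt8 and Krt18 in 33 and 28 cells, E-cadherin (Cdh1; chromosome 8, 106603351 to 106670246, plus strand) in 18 and Epcam in 17. Among 13 mesenchymal genes 8 were, with Fn1, Cdh2 and Vim in 47 cells each and Cdh11 in 31. Vim and Krt8 had the largest excess variability of their lists, with maxima of 978 and 648 FPKM.

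Genes of 4 signalling pathways, among them receptors and ligands as well as targets, were examined. The BMP response list had 7 of 9 members in at least 25% of cells, with Id3 and Id1 in 47 cells each (medians 748 and 209 FPKM), Id2 in 40 and Smad7 in 35. The FGF response list had 7 of 8, led by Spry2 in 48 cells, Dusp6 in 44, Fgfr1 in 41 and Etv5 in 39. The WNT response list had 7 of 9, with Znrf3 in 47 cells, Lef1 in 40, Rspo3 in 36 and Tcf7 in 33. The NOTCH response list had 5 of 10, with Hes1 in 48 cells, Hey1 in 31, Jag1 in 25 and Notch1 in 20, and Hes5, Heyl and Dll4 in none.

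All 25 S phase members, such as Pcna, Mcm7 and Rrm2 (48 cells each), and all 26 G2 and M phase members, such as Birc5 and Top2a (47 cells each), reached the 25% mark. The glycolysis and hypoxia list had 9 of 14 members, with Ldha and Aldoa in 48 cells, Pgk1 in 47 and Hk2 and Pfkl in 43. The immediate early and heat shock list had 7 of 12, with Fos in 44 cells, Jun in 42, Ier2 in 40 and Egr1 in 36. The p53 and apoptosis list had 7 of 10, with Bax in 46 cells and Ccng1 in 37. In all, 175 of the 314 listed genes were detected in at least 25% of cells.

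Genes that differed most between cells included regulators of pluripotency and early mesoderm. Of 6266 genes with a mean of at least 5 FPKM, 680 (10.9%) had a squared coefficient of variation over 2-fold above the trend for their mean. Among the 25 with the largest excess, 11 were not short RNAs: Dppa5a, Pgam2, Trh, Mt1, Rhox5, Cer1, Myl7, Gm12238, Clu, Etv2 and Utf1. Trh stood 28.7-fold above the trend, Cer1 17.2-fold and Etv2 13.8-fold, and Dppa5a, a gene of pluripotent cells, reached 3538 FPKM in 1 cell and was detected in 21. Pgam2 rested on a single cell, which held 83.6% of its summed FPKM, and 1 cell held 54.3% for Myl7. The other 14 were microRNA or small nucleolar RNA rows: Mir3470a, Snord47, Mir1196, Mir3091, Snord104, Mir1954, Snora33, Snora30, Snora68, Snora26, Snora31, Mir682, Snora70 and Snord22. Such rows took from 2.21% to 96.6% of a cell's summed FPKM, and Mir3470a, 77 bp long, was listed at up to 11900000 FPKM. Without short RNA rows 664 of 6239 genes were variable.

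Members of most programmes correlated with each other across cells more than matched random genes did, though in several lists only weakly. Of 20 lists with 3 or more usable members, 14 had a mean pairwise correlation at or above the 98th percentile of matched random lists, where 0.4 would be by chance. The G2 and M phase list reached a mean rho of 0.45, the epithelial list 0.42, the pluripotency list 0.30, the endothelial list 0.24, the paraxial list 0.21 and the cardiac and lateral plate list 0.18, each at a percentile of 100. The immediate early (0.17, percentile 100), BMP response (0.15, percentile 99.9), smooth muscle (0.15, percentile 99.3), S phase (0.13, percentile 100), mesenchymal (0.10, percentile 99.9), primitive streak (0.096, percentile 99.95) and p53 (0.088, percentile 98.4) lists were also called. The skeletal myogenic list (0.21, percentile 98.03) rested on 3 members, among them Eya1 and Pax3, developmental regulators also used outside muscle, and its value was -0.11 after regression on the capture site number. The contractile (percentile 93.4), WNT (19.6), NOTCH (65.8), FGF (96.1), glycolysis (92.2) and housekeeping (78.7) lists were not called. Over up to 11 other settings, the pluripotency, paraxial, cardiac and lateral plate, epithelial and 2 cell cycle lists kept their calls in all; endothelial and immediate early did in 10 of 11, primitive streak, mesenchymal and BMP in 9 of 11, p53 in 5 of 11, smooth muscle in 4 of 11 and skeletal myogenic in 4 of 8. Rescaling each cell to a total of 1000000 left 9 lists called, among them S phase, whose mean rho rose to 0.39. Primitive streak, smooth muscle, mesenchymal, BMP and p53 lost their calls. With short RNA rows left out before rescaling, a setting chosen after the data had been seen, all 14 lists kept theirs. At sites up to 48 alone, smooth muscle (percentile 64.4), immediate early (93.4) and p53 (54.7) were no longer called, and at sites above 48 alone streak, endothelial, smooth muscle and mesenchymal were not, so smooth muscle was called in neither part.

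**Figure D3:**
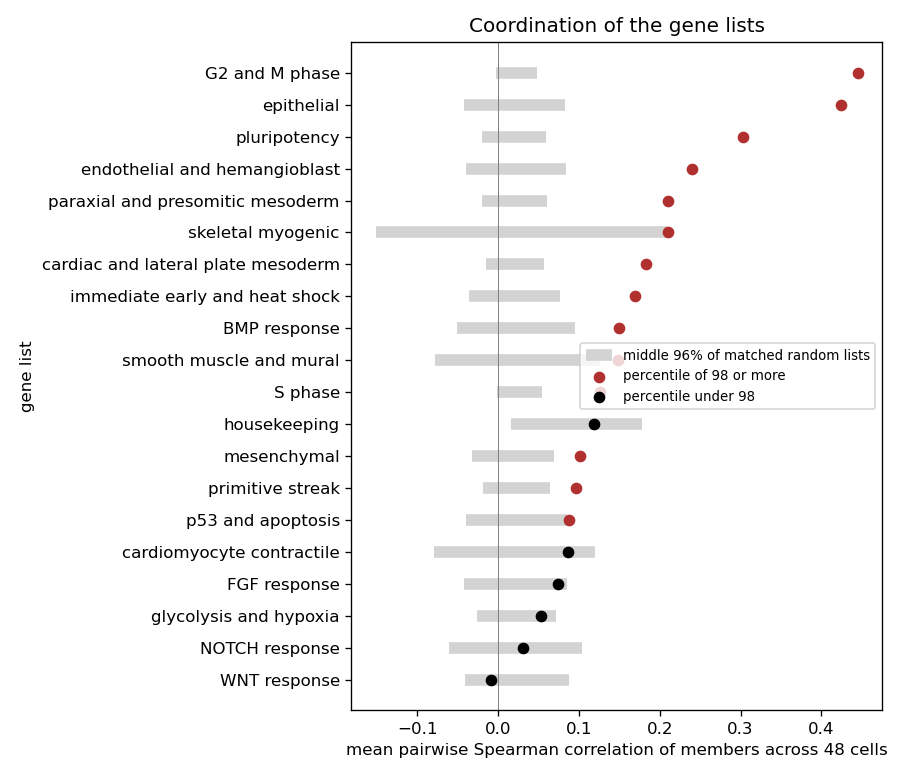
Mean pairwise Spearman correlation of each list's members over the 48 cells (points, horizontal axis) against the range of matched random lists (grey bars). Red points lie at or above the 98th percentile; the G2 and M phase list was highest at 0.45 and the WNT response list lowest at -0.0087.

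Programmes also differed in how variable they were. Of 18 lists with enough members, 7 had a median excess variability at or above the 98th percentile of matched lists: pluripotency, primitive streak, paraxial, contractile, endothelial, epithelial and BMP response. Only members with a mean of at least 5 FPKM entered, so some values rest on few genes. These were 4 of 14 contractile, 4 of 21 endothelial, 4 of 9 BMP, 5 of 18 paraxial and 5 of 10 epithelial members. A high value in 1 cell could carry a gene over this filter, as for Actc1, with a mean of 5.67 and a maximum of 158 FPKM. The cardiac and lateral plate list (percentile 89.02), the mesenchymal list (88.7) and the S phase list (57.4) were not among them.

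Epithelial and mesenchymal programmes moved apart between cells, and pluripotency genes moved with the epithelial side. The epithelial and mesenchymal scores had rho = -0.53 (r = -0.58, percentile 0.01; r = -0.54 without the 2 farthest cells). Pluripotency correlated with epithelial genes at rho = 0.59 (r = 0.46, percentile 99.9) and with mesenchymal genes at rho = -0.48 (r = -0.41, percentile 0). The cells with the highest pluripotency scores (1.42 to 1.81) were not the most epithelial, however. Their epithelial scores ran from -0.13 to 0.63, while another cell reached 1.72. Paraxial and cardiac and lateral plate genes rose with mesenchymal genes (rho = 0.51 and 0.43) and moved apart from epithelial genes (rho = -0.39 and -0.40), while the 2 mesoderm lists, without the shared Pdgfra, had no relation to each other (rho = 0.010, percentile 47.9). Pluripotency moved apart from cardiac and lateral plate (rho = -0.31) and smooth muscle genes (rho = -0.30) and together with glycolysis genes (rho = 0.52), though both of these scores rose with the number of detected genes (rho = 0.51 each), and after regression on that number the relation fell to rho = 0.32 and was not called. The remaining calls were contractile with cardiac (rho = 0.43) and smooth muscle genes (rho = 0.51), and mesenchymal with endothelial (rho = 0.37) and smooth muscle genes (rho = 0.39).

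In all, 14 of 54 relations were called, 8 together and 6 apart, where 2.16 would be by chance at a rate of 4% per pair. That rate is approximate, since the less extreme of 2 percentiles was kept. The pairs reuse 11 lists, so the 14 calls are not independent of each other. Within sites up to 48 the epithelial and mesenchymal scores had rho = -0.62 (percentile 0.12) and within higher sites rho = -0.40 (percentile 2.61); pluripotency with epithelial genes had rho = 0.72 and 0.45, pluripotency with mesenchymal genes -0.55 and -0.30, paraxial with mesenchymal genes 0.60 and 0.38, and endothelial with mesenchymal genes 0.50 and 0.044 (percentile 45.2 at higher sites). Of the called relations, 12 could be computed in both parts; while 9 were called at sites up to 48, 0 were called at higher sites, so none held its call within both parts. At higher sites cardiac with mesenchymal (rho = 0.45, percentile 91.4), pluripotency with glycolysis (0.55, percentile 97.6) and pluripotency with cardiac genes (-0.31, percentile 2.95) were no weaker than over all cells. The rho of every other called relation computed there was nearer to 0 than over all cells. Over 11 other settings (10 for pairs with contractile genes), calls were kept in 10 for epithelial with mesenchymal, with pluripotency and with paraxial genes and for pluripotency with mesenchymal genes; in 9 for pluripotency with smooth muscle, paraxial with mesenchymal and cardiac with epithelial genes; in 8 for mesenchymal with cardiac and with smooth muscle and for contractile with smooth muscle genes; in 7 for pluripotency with cardiac genes; in 5 for endothelial with mesenchymal and pluripotency with glycolysis genes; and in 3 for cardiac with contractile genes. Without the few-gene cells, 6 of the 8 together and 4 of the 6 apart kept their calls; pluripotency and epithelial with cardiac genes were the 2 called apart that did not. After rescaling to a common total, 2 of the 8 relations called together kept their call; all 4 with mesenchymal genes (paraxial, cardiac, endothelial and smooth muscle) lost theirs although their rho did not fall, while all 6 relations called apart kept it with a rho nearer to 0. With short RNA rows left out before rescaling, all 14 relations kept their calls.

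**Figure D4:**
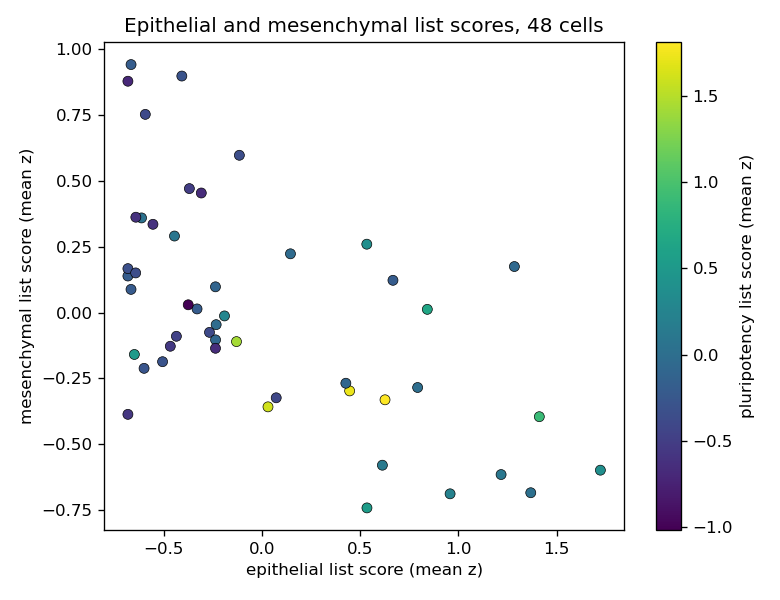
Epithelial (horizontal) and mesenchymal (vertical) list scores, each the mean z-score of its members, for the 48 cells (points), coloured by the pluripotency list score. The scores moved apart (rho = -0.53). The cells with the highest pluripotency scores lay neither among those with the highest mesenchymal scores nor among those with the highest epithelial scores.

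Kdr and Pdgfra, surface receptors used to sort mesoderm subsets, were co-detected in 16 cells (33.3%, exact 95% interval 20.4% to 48.4%), with Kdr alone in 6, Pdgfra alone in 15 and neither in 11. Independent detection would give 14.2 cells with both. Kdr lies on chromosome 5 from 75932827 to 75978458 (minus strand) and Pdgfra from 75152292 to 75198215 (plus strand). Their levels had rho = 0.27 (r = 0.22, percentile 95.6 among matched gene pairs), which was not called, with rho = 0.34 at sites up to 48 and 0.17 at higher sites. The number of cells with both depended on the threshold, at 24 with 0.1 FPKM and 7 with 10 FPKM.

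S phase and G2 and M phase scores moved apart between cells, with rho = -0.34 (r = -0.26, percentile 0, and r = -0.35 without the 2 farthest cells). At sites up to 48 rho was -0.65 (percentile 0.04), and at higher sites it was -0.22 (percentile 34.5), where it was not called. The G2 and M phase score fell with the capture site number (rho = -0.46).

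Clustering on the 500 most variable genes gave 4 clusters of 26, 13, 5 and 4 cells, but the separation was no better than that of shuffled data: the mean silhouette was 0.296, and 42 of 100 matrices with each gene permuted over cells reached as high a value (median 0.291). The cluster of 5 cells (10.4%, exact 95% interval 3.47% to 22.7%) was pluripotent-like by 4 list markers among its 10 leading genes. These markers were themselves used to cluster, so the name is a description only. This cluster is described by Mir1935, Dppa5a, Dppa3, Dppa4 and Mt2. Mesp1 was detected in 4 of its cells, 4 lay at sites up to 48, and its median of genes detected was 6744. The other 3 had under 3 markers of any cell type list among their 10 leading genes and stayed unnamed, though 3 genes of the epithelial state list (Krt18, Cldn6 and Krt8) were among those of the 13-cell cluster. They are described by Snora70, Crabp1, Egr1, Asb4 and Pdgfra (26 cells), by Krt18, T, Tdgf1, Pim2 and Calca (13 cells), and by Mir3470a, Ube2l6, BC028528, Mir669h and Zfand2b (4 cells). The number of clusters ranged from 3 to 5 over the alternatives.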

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

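The division of cells by capture site, the regression on capture site, the removal of short RNA rows, rescaling without them, and leaving out few-gene cells for Mesp1 and the cell cycle lists were chosen after the data had been seen; the other settings were fixed beforehand. No paired analysis was possible because the series has 1 group. The share of cells with Mesp1 stayed within its counting interval, and the numbers of list members detected and of variable lists within 1.5-fold, under every setting run for them. Both cell cycle lists stayed called, but coordination of S phase rose to 0.39 after rescaling to a common total. The median for genes detected per cell was 7649 at 0.1 FPKM and 3904.5 at 10 FPKM, and cells with both Kdr and Pdgfra numbered 24 and 7, as the threshold sets. The variable genes numbered 1344 without the filter on the mean, when 10598 genes entered. Coordinated lists numbered 9 of 21 after rescaling to a common total and 9 of 18 at sites above 48. Relations called together numbered 5, of which 2 were among the original 8, and apart 11 of 65 after rescaling; they numbered 1 and 0 of 36 at sites above 48, with 23 cells. Relations apart numbered 11 of 45 at sites up to 48, and 12 of 77 after rescaling without short RNA rows, when more relations could be computed. No called relation kept its call in every setting; epithelial with mesenchymal, pluripotency with epithelial, pluripotency with mesenchymal and paraxial with epithelial genes were called in 10 of 11. The S phase relation with G2 and M phase was -0.22 at sites above 48, no longer called. The coordination of the skeletal myogenic list turned to -0.11 after regression on the capture site. Clusters numbered 5 with 200 genes and 3 with 1000 genes, a pseudocount of 0.1, without the few-gene cells, or without short RNA rows; the largest held 35 cells with 1000 genes and 33 with the pseudocount of 0.1. The lists and relations that lost their calls on rescaling kept them when short RNA rows were left out first. Apart from this, and where the threshold, the filter or the number of cells or relations changed by construction, the cause was not tested. Depth is unknown, so no limit from depth can be given for a gene listed at 0.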

Other observations

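All tests and values in this part were chosen after the data had been seen, except the regression of the epithelial and mesenchymal lists on the number of detected genes. Mesp1 level at day 4, after doxycycline had ended, was set against 11 lists. Of these, 2 were called: paraxial mesoderm (rho = 0.47, percentile 99.99) and cardiac and lateral plate mesoderm (rho = 0.34, percentile 98.1). The latter lay close to the limit of 98. Pdgfra was kept in both lists here, so the 2 calls are not fully separate. Paraxial genes had rho = 0.31 at sites up to 48 and 0.65 at higher sites, and cardiac genes 0.49 and 0.13. The endothelial list was not called with Mesp1 (rho = -0.026, percentile 48.5), with rho = 0.31 at sites up to 48 and -0.33 at higher sites. Etv2, set against the same 11 lists, was called with the other endothelial genes alone (rho = 0.37, percentile 98.9); with pluripotency genes it had rho = -0.29 at a percentile of 2.27.

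Clustering without short RNA rows, run because such rows led some clusters, gave 3 clusters of 32, 12 and 4 cells. Its silhouette of 0.327 lay above all 100 permuted matrices (highest 0.240), unlike that of the planned clustering, which it does not replace. Permuting each gene on its own removes all correlation between genes. A gradual change over cells could therefore also exceed it, so the comparison does not show that the clusters are separate groups. The cluster of 12 cells is described by Krt18, T, Calca, Cldn6 and Pim2, that of 32 by Crabp1, Capn6, Pmp22, Id2 and Hand1, and that of 4 by Dppa5a, Dppa3, Zfp42, Dppa4 and Mt2.

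The first pattern weighed is the fall of detected genes with capture site. It was also present within the 32 cells of the largest cluster made without short RNA rows (rho = -0.82), which argues against the split into these clusters as its source. The clusters are not shown to be separate kinds of cells, so other differences between cells are not excluded. The G2 and M phase score, for example, fell with the site number (rho = -0.46) and rose with genes detected (rho = 0.48). Lower sequencing depth would raise the smallest values above 0, but their median over the 100 smallest fell with the site number (rho = -0.34), as did the lowest 1% (rho = -0.47) and 5% (rho = -0.57) quantiles. These values stand in for depth, which the table does not hold. They also depend on transcript length and on which genes a cell detects, the pattern in question, so they cannot exclude lower depth. RNA capture or amplification that differed along the device may be a source and was not tested. No other biological explanation was tested.

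The second is the opposition of epithelial and mesenchymal genes. After regression on the number of detected genes it stood at rho = -0.60 (percentile 0.01), which argues against detection as the whole cause. After regression on the capture site it stood at rho = -0.56 (percentile 0.02), which argues against a linear trend along the device. The epithelial and mesenchymal scores went the same way with detected genes (rho = 0.22 and 0.055) and with capture site (rho = -0.089 and -0.088). Removing such trends was therefore unlikely to weaken the opposition, and the regressions add little to these values. A test of position within the 2 parts of the device, a division chosen after the data had been seen, was weaker: within higher sites rho was -0.40 over 23 cells, past the bound of -0.3 written before this value was seen, but by less than its spread of 0.21 (SD of 1000 resamplings, a criterion added once the value was known), so position in a form other than a linear trend cannot be told apart. No biological explanation was tested, since the series has 1 group.

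The third is the group of 4 cells with high pluripotency genes. All 4 lay at sites up to 48, as did 21 of the other 44 cells, and their median of genes detected was 6726.5 against 6204.5. Short RNA rows took over 50% of FPKM in 3 of the 4 (68.5% to 74.1%) and in 8 of the other 44, and 3.89% in the remaining one; whether this bears on the group was not tested. Undifferentiated stem cells and early germ cells are candidate explanations, set against a panel of 12 naive pluripotency and 15 germ cell genes drawn up after the leading genes had been seen. Outside the genes used to cluster, 4 of 8 naive genes and 7 of 13 germ cell genes, several of which stem cells also express, reached 1 FPKM in at least 3 of the 4 cells. Klf5, Stra8 and Itgb3 reached it in none of the 4. Because the panels overlap in this way, such counts could hardly separate the 2 explanations, which cannot be told apart. Part of both counts is shared with the other 44 cells, of which the naive genes were detected in 22 (Klf4), 3 (Klf2), 3 (Tfcp2l1) and 2 (Esrrb), and the germ cell genes in 23 (Alpl), 14 (Kit), 11 (Prdm1), 3 (Tfap2c), 3 (Dnd1), 1 (Nanos3) and 1 (Dppa2); Dppa3 (chromosome 6, 122626410 to 122630272, plus strand), which was used to cluster, was in 2. Within the 4 cells, Nanos3, Tfap2c, Dppa2 and Alpl were detected in all 4, as were Esrrb, Klf2 and Klf4. The naive genes Nr0b1, Tet2 and Gbx2 and the germ cell genes Prdm14, Ddx4 and Tex19.1 were each in 1, and Dazl was in 2. T, which was used to cluster, was in 0 of the 4 and in 26 of the other 44. Mesp1 and Mixl1, also used to cluster, did not share this absence. Each was in 3 of the 4 and in 27 of the other 44. Their medians were 17.4 and 31.6 FPKM in the 4 cells, against 7.10 and 20.5 FPKM in the others.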
